A study of Mus musculus with 67 samples.

How the data were processed

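RNA libraries of retina and RPE from photosensitive Abca4-/- Rdh8-/- mice were analysed, 33 in all. The retina groups were NB (n = 6), 6h (n = 3), 1d (n = 4) and 3d (n = 4), and the RPE groups NB (n = 5), 6h (n = 3), 1d (n = 4) and 3d (n = 4). NB is not spelled out in the labels and served as the reference; the labels do not give the event from which the times count. Per the labels' protocols, both eyes of 1 mouse were pooled, retina was kept in RNAlater, RPE cells were shaken off the eyecup into RNAprotect before the choroid was taken out, and libraries were stranded mRNA libraries. The ATAC libraries were not analysed here.

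Per the submitters' processing notes, Trimmomatic, STAR and edgeR were used with the GRCm38 genome; the notes give neither versions nor the read counter. Each deposited signal value is, per the file headers and the values, a CPM that the authors computed on an effective library size (a library total times a normalization factor), so that column sums differ between libraries. Every signal value was checked to be a whole multiple of the library's value for 1 read, within 0.01 of a read, and reads were recovered by that step. The authors had filtered out low genes by a rule that is not stated. The deposited log2 fold changes were made by the authors for each time against NB and shrunk with a prior count, per the file headers. The deposited p-value of each gene is unadjusted and, per the file headers, of the kind edgeR gives when testing against a minimum fold, whose size is not stated. Retina and RPE tables were normalized separately. Gene symbols were matched by Ensembl identifier, leaving 6 retina and 7 RPE identifiers unmatched, which stayed in the tests.

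Recovered depth fell into a deeper and a shallower set. In retina 5 libraries (6h, NB A1, NB A2) held 22.6 to 32.4 M reads, and 12 libraries (NB B1 to B4, 1d, 3d) held 9.45 to 15.2 M reads. In RPE 4 libraries (6h, NB A1) held 23.1 to 26.8 M reads, and the other 12 held 11.5 to 14.4 M reads. The letters were assigned here from the column names, in which NB numbers repeat between the sets, so that NB libraries were matched to the group and not to single samples. The 1d to 6h contrasts therefore cross the sets.

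Values were tested as log2(CPM + 0.5) with limma 3.58.1 (linear fit of all groups of a tissue, moderated variance with a trend, Benjamini-Hochberg adjustment, threshold 0.05) in R 4.3.3, for genes with a CPM of at least 1 in at least 3 libraries (16926 in retina, 16712 in RPE). The added 0.5 shrinks fold changes of low genes. The difference between the tissue responses was tested in 1 fit of both tissues (15105 genes), each tissue against its own NB. Errors of CPM are SD and errors of log2 fold changes SE. Adjusted p-values printed for genes are those of limma. A gene was called higher or lower when it passed the threshold, and "not past" otherwise.

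Gene lists (34) were tested with limma's camera at a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over all lists and the comparisons with NB; contrasts of times and of tissues were adjusted among themselves. They covered retinal cells (rods, cones, bipolar cells, amacrine, horizontal and ganglion cells, resting Muller glia, glial reactivity, microglia and macrophages), RPE (visual cycle, RPE identity, melanin synthesis, phagocytosis and lysosome, AMD risk loci), responses (immediate early, heat shock, unfolded protein response, NRF2, interferon, complement, chemokines, cell death, cell cycle, extracellular matrix, chromatin and DNA methylation, circadian clock), metabolism (glycolysis, oxidative phosphorylation, mitochondrially encoded, cholesterol synthesis) and other cells (endothelium, fibroblast and pericyte, red blood cells, T cells, lens). Neutrophil genes had fewer than 3 tested members and were not tested, and T cell genes were tested in RPE alone. Beside each list the calls among its members are given, and the calls when members were adjusted over the list alone.

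The genes named were set by a rule: for each time against NB, up to 8 called genes with the largest positive and 8 with the largest negative log2 fold change among those whose groups do not overlap and whose mean CPM is at least 2 in the higher group; 5 in each direction for contrasts of times and tissues; up to 4 members of each list with the smallest adjusted p; and Abca4 and Rdh8. Some genes that met the rule are not reported here. Krt5 and the genes of carry-over bounds were named for their levels, after these were seen. Surface epithelium markers (18) were listed after Krt5 had been seen in RPE libraries.

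Test, filter, lists, the rule for genes and most alternatives were fixed before the data were examined. Alternatives were pseudocounts of 0.1 and 2, no filter, TMM rescaling of the CPM values, a 2-fold minimum, edgeR 4.0.16, DESeq2 1.42.0, limma array weights, fits of a pair of groups alone, a replicate block, leaving out each library in turn, and the authors' deposited p-values with adjustment. Added after seeing the data were a set term, NB libraries of the same set alone (within set), median-ratio scaling, library totals alone, and fits without RPE NB B3, 1d 4 and 3d 2 (and NB A1) or without genes at least 4-fold higher in NB retina.

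Tests were first run on data simulated from the real means and library sizes with 200 changed genes. Retina comparisons recovered 59.7 to 79.1% of genes changed 1.5-fold, 82.1 to 91.0% at 2-fold and 98.5 to 100% at 4-fold, and RPE comparisons 14.9 to 28.4%, 56.7 to 71.6% and 95.5 to 97.0%, with 3 to 12 unchanged genes called. Tissue differences gave 17.9 to 29.9%, 53.7 to 74.6% and 92.4 to 98.5%, with 14. Library and set differences moved the real counts, so these rates may not hold there.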

Results

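Abca4 and Rdh8, the genes named in the genotype, were read in every group. Retinal Abca4, which codes for a transporter of outer segments, averaged 797 ± 96.3 CPM in NB (SD, n = 6), 465 ± 9.97 at 6h (n = 3), 388 ± 42.4 at 1d (n = 4) and 448 ± 9.19 at 3d (n = 4). Rdh8, a retinol dehydrogenase gene, averaged 40.4 ± 6.08, 43.7 ± 5.75, 37.7 ± 6.20 and 45.9 ± 3.34 CPM there. In RPE the groups had n = 5, 3, 4 and 4, with Abca4 at 240.2 ± 27.2, 199 ± 25.8, 193 ± 36.6 and 251 ± 36.0 CPM and Rdh8 at 2.86 ± 0.656, 6.50 ± 2.92, 4.55 ± 0.830 and 5.46 ± 1.69. The retinal fall of Abca4 passed the test at each time (log2 fold change -0.77 ± 0.08 SE, -1.04 ± 0.08 and -0.82 ± 0.08). A read count over a whole gene checks nothing about its deletion.

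At 6h the retina gained cytokine and immediate early transcripts against NB (n = 3 and n = 6). Lif, a cytokine gene of the interleukin-6 family, rose from 0.719 ± 0.266 to 48.0 ± 5.86 CPM (log2 fold change 5.34 ± 0.21, adjusted p = 8.68e-13). Osmr, a receptor gene of the same family, rose from 9.0 ± 1.56 to 106 ± 3.61 CPM (log2 fold change 3.51 ± 0.12, adjusted p = 7.16e-14). The transcription factor gene Cebpd rose from 3.99 ± 1.14 to 60.8 ± 4.78 CPM (log2 fold change 3.80 ± 0.15, adjusted p = 8.68e-13). Fosl1, an AP-1 subunit gene, rose from 0.0268 ± 0.0361 to 21.5 ± 2.52 CPM (log2 fold change 5.38 ± 0.15, adjusted p = 6.80e-15), a fold that the added 0.5 understates because NB lay near 0. Large rises on the log2 scale were also seen for Icam1 (3.68 ± 0.18), Zfp36 (3.4 ± 0.23), Gbp2b (3.37 ± 0.21) and Bcl3 (3.36 ± 0.15), which act in adhesion, mRNA decay, interferon defence and NF-kappaB signalling. Slc16a3, a lactate transporter gene, fell from 56.9 ± 8.97 to 15.1 ± 0.959 CPM (log2 fold change -1.87 ± 0.11, adjusted p = 2.05e-10). The adenylate kinase gene Ak4 fell (49.5 to 17.6 CPM, log2 -1.46 ± 0.10). Less characterized genes fell too, Ccdc24 (-1.55 ± 0.15), Ube4bos1 (-1.82 ± 0.19), AC166748.1 (-1.75 ± 0.20), Dleu7 (-1.60 ± 0.20), BC065403 (-1.58 ± 0.20) and Meig1 (-1.51 ± 0.22).

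The glial reactivity list counted 21 higher, 0 lower and 2 not past of 23 (21 and 0 adjusted over the list alone). Their median was 2.17, adjusted p = 9.55e-22 (adjusted p = 0.0661 with an estimated correlation). Stat3, the transcription factor under these cytokine receptors, rose from 68.0 ± 3.39 to 309 ± 39.3 CPM (log2 fold change 2.17 ± 0.07, adjusted p = 3.42e-14). The metallothionein gene Mt2 rose (11 to 109.8 CPM, log2 3.27 ± 0.14). Immediate early genes rose (14 higher, 0 lower, 6 not past, 16 and 0 adjusted over the list alone). The median, 1.75, had adjusted p = 4.58e-09, but adjusted p = 0.236 with an estimated correlation. Jun (41.2 to 295 CPM, log2 2.83 ± 0.09) and Atf3 (4.36 to 24.9 CPM, log2 2.41 ± 0.14), bZIP factors, rose. Chemokine and cytokine genes rose (9 higher, 1 lower, 2 not past, 9 and 1 adjusted over the list alone). At median 1.90 the list had adjusted p = 2.11e-08 (adjusted p = 0.135 with an estimated correlation). Ccl2, which attracts monocytes, rose (0.0213 to 3.1 CPM, log2 2.79 ± 0.24). Interferon and antigen presentation genes rose (14 higher, 0 lower, 14 not past, 16 and 0 adjusted over the list alone). Their median was 0.46, adjusted p = 1.86e-05 (adjusted p = 0.497 with an estimated correlation). Irf1 (6.98 to 25.4 CPM, log2 1.80 ± 0.11) and Gbp2 (2.41 to 24.7 CPM, log2 3.14 ± 0.20), interferon-induced genes, rose. Cell death genes were higher (10 higher, 0 lower, 6 not past, 10 and 0 adjusted over the list alone). A median of 0.56 had adjusted p = 8.63e-05, but adjusted p = 0.0985 with an estimated correlation. The death receptor genes Tnfrsf1a (7.30 to 35.9 CPM, log2 2.23 ± 0.12) and Fas (0.566 to 7.27 CPM, log2 2.91 ± 0.21) rose. Complement genes rose (7 higher, 1 lower, 6 not past, 7 and 1 adjusted over the list alone). The median, 0.42, had adjusted p = 0.00791, but adjusted p = 0.364 with an estimated correlation. C3 (1.73 to 6.08 CPM, log2 1.55 ± 0.22) and the C1 inhibitor gene Serping1 (7.61 to 16.3 CPM, log2 1.05 ± 0.16) rose. Heat shock genes were higher (9 higher, 0 lower, 9 not past, 9 and 0 adjusted over the list alone). At median 0.29 the list had adjusted p = 0.00163 (adjusted p = 0.385 with an estimated correlation). Hmox1, the heme oxygenase gene, rose (3.52 to 32.6 CPM, log2 3.03 ± 0.19).

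Among 30 rod genes 0 passed the test as higher, 21 as lower and 9 did not (0 and 22 adjusted over the list alone). With a median of -0.51 the list had adjusted p = 3.91e-09, but adjusted p = 0.437 with an estimated correlation. Nr2e3, a rod-fate receptor gene, fell from 564 ± 69.9 to 218 ± 12.4 CPM (log2 fold change -1.36 ± 0.14, adjusted p = 4.77e-07). Rcvrn (811 to 406 CPM, log2 -1.0 ± 0.10), Gnb1 (5259.8 to 2646 CPM, log2 -0.99 ± 0.12) and Rom1 (2039.7 to 1077 CPM, log2 -0.92 ± 0.11), which code for recoverin, a transducin subunit and a disc-rim protein, fell. Glycolysis genes fell (0 higher, 13 lower, 6 not past, 0 and 14 adjusted over the list alone). A median of -0.34 had adjusted p = 2.59e-07, but adjusted p = 0.202 with an estimated correlation. The enzyme genes Pfkl (445 to 259 CPM, log2 -0.78 ± 0.05), Pgam1 (303 to 199.6 CPM, log2 -0.60 ± 0.04) and Pgk1 (583 to 399 CPM, log2 -0.55 ± 0.05) fell. Oxidative phosphorylation genes fell by less (0 higher, 20 lower, 8 not past, 0 and 21 adjusted over the list alone). The median, -0.18, had adjusted p = 2.39e-06, but adjusted p = 0.364 with an estimated correlation. RPE identity genes were higher in the 6h retina samples (13 higher, 3 lower, 8 not past, 14 and 3 adjusted over the list alone). At median 0.39 the list had adjusted p = 9.31e-04 (adjusted p = 0.437 with an estimated correlation). The RPE genes Cdh3, a cadherin, and Kcnj13, a channel, rose (2.69 to 15.0 CPM, log2 2.30 ± 0.19) and (7.82 to 29.4 CPM, log2 1.88 ± 0.23). Chromatin and DNA methylation genes were higher (16 higher, 4 lower, 12 not past, 18 and 4 adjusted over the list alone). Their median was 0.18, adjusted p = 0.00551 (adjusted p = 0.437 with an estimated correlation). Crebbp, which codes for an acetyltransferase, rose (80.3 to 125 CPM, log2 0.64 ± 0.07), while the demethylase gene Tet2 fell (129.8 to 95.1 CPM, log2 -0.45 ± 0.06). Clock genes were not called (6 higher, 4 lower, 7 not past, 6 and 4 adjusted over the list alone). A median of 0.05 had adjusted p = 0.412. Fibroblast and pericyte genes were not called (0 higher, 0 lower, 12 not past, 0 and 0 adjusted over the list alone). The median, 0.24, had adjusted p = 0.340. Mitochondrially encoded genes were not called (3 higher, 0 lower, 10 not past, 1 and 0 adjusted over the list alone). At median 0.03 the list had adjusted p = 0.434.

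Across the 6h and NB retinas 5991 of 16926 genes passed the test, 2854 higher and 3137 lower. Of these, 455 changed by at least 2-fold (7521 genes had an unadjusted p under 0.05). In the authors' deposited table, 852 genes passed once p was adjusted, 850 of which passed here in the same direction. All 6h libraries belong to the deeper set, and against the 2 NB libraries of that set 5446 genes passed. In this contrast 18 gene lists were called, of which 3 (melanin synthesis, unfolded protein response and phagocytosis) lost the call when at least 1 library was left out.

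Glial reactivity transcripts were among those higher in retina at 1d than in NB (n = 4 and n = 6). Prss56, a serine protease gene, rose from 2.74 ± 0.452 to 357 ± 117 CPM (log2 fold change 6.74 ± 0.19, adjusted p = 2.12e-15). Serpina3n, a secreted protease inhibitor gene, rose from 7.09 ± 2.98 to 392 ± 79.6 CPM (log2 fold change 5.76 ± 0.22, adjusted p = 1.72e-13). Edn2, a vasoactive peptide gene, rose from 3.00 ± 1.26 to 81.4 ± 14.1 CPM (log2 fold change 4.63 ± 0.24, adjusted p = 1.09e-11). Nlrc5, an activator of class I antigen presentation, rose from 0.864 ± 0.206 to 33.4 ± 9.76 CPM (log2 fold change 4.60 ± 0.18, adjusted p = 2.61e-13). Further large rises were Bcl3 (4.99 ± 0.14), Lad1 (4.98 ± 0.18), Tnnt2 (4.73 ± 0.18) and CT025671.4 (4.41 ± 0.13). Glul, the glutamine synthetase gene of Muller glia, fell from 2698 ± 94.5 to 629 ± 35.6 CPM (log2 fold change -2.10 ± 0.06, adjusted p = 2.57e-15). Hdc, which makes histamine, fell from 18.5 ± 5.56 to 1.72 ± 0.658 CPM (log2 fold change -3.10 ± 0.23, adjusted p = 2.11e-09). Other falls included Glb1l3 (-3.02 ± 0.28), Fndc1 (-2.19 ± 0.21), Rncr4 (-2.10 ± 0.15), Rabgef1 (-2.03 ± 0.13) and Ccdc24 (-2.02 ± 0.13).

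The rod list counted 0 higher, 30 lower and 0 not past of 30 (0 and 30 adjusted over the list alone). Their median was -1.26, adjusted p = 6.42e-18 (adjusted p = 0.360 with an estimated correlation). Pdc, a transducin-binding phosphoprotein gene, fell from 2500.3 ± 259 to 756 ± 172 CPM (log2 fold change -1.75 ± 0.11, adjusted p = 2.50e-10). Nrl, the rod-fate regulator, fell from 1985 ± 113 to 626 ± 169.6 CPM (log2 fold change -1.70 ± 0.12, adjusted p = 6.38e-10). Gngt1 (1019 to 356 CPM, log2 -1.53 ± 0.09) and Cnga1 (799 to 305 CPM, log2 -1.41 ± 0.09), a transducin subunit and the rod channel, fell. Cone genes were lower (3 higher, 8 lower, 0 not past, 3 and 8 adjusted over the list alone). A median of -0.71 had adjusted p = 0.0243, but adjusted p = 0.408 with an estimated correlation. The arrestin gene Arr3 fell (385 to 157 CPM, log2 -1.31 ± 0.09) and the transducin gene Gnb3 rose (388 to 959 CPM, log2 1.3 ± 0.05). Hk2 (592 to 264 CPM, log2 -1.15 ± 0.10) and Ldha (972 to 666 CPM, log2 -0.55 ± 0.06), of glycolysis, fell. Cholesterol synthesis genes were not called (1 higher, 12 lower, 7 not past, 1 and 12 adjusted over the list alone). The median, -0.16, had adjusted p = 0.0835. They were called against the NB libraries of the same set (median -0.20, adjusted p = 0.0221) and without NB A1 (adjusted p = 0.0444).

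The interferon and antigen presentation list counted 28 higher, 0 lower and 0 not past of 28 (28 and 0 adjusted over the list alone). Their median was 2.01, adjusted p = 7.63e-18 (adjusted p = 0.236 with an estimated correlation). H2-D1, a class I antigen gene, rose from 31.6 ± 1.81 to 142 ± 15.9 CPM (log2 fold change 2.15 ± 0.07, adjusted p = 3.91e-14). Stat2, an interferon signal transducer, rose from 60.3 ± 4.11 to 189 ± 22.8 CPM (log2 fold change 1.64 ± 0.07, adjusted p = 9.13e-13). Glial reactivity genes rose (22 higher, 0 lower, 1 not past, 22 and 0 adjusted over the list alone). Their median was 3.07, adjusted p = 5.12e-21 (adjusted p = 0.0661 with an estimated correlation). The signal genes Stat3 (68.0 to 380.3 CPM, log2 2.48 ± 0.06) and Socs3 (3.27 to 68.8 CPM, log2 4.21 ± 0.12) rose, and the protease inhibitor gene A2m (11.7 to 225 CPM, log2 4.2 ± 0.12). Microglia and macrophage genes were higher (13 higher, 3 lower, 7 not past, 14 and 3 adjusted over the list alone). A median of 0.53 had adjusted p = 0.00296, but adjusted p = 0.437 with an estimated correlation. Cd68 (1.82 to 8.38 CPM, log2 1.94 ± 0.13) and Lgals3 (9.09 to 51.1 CPM, log2 2.48 ± 0.24), phagocyte genes, rose, while the homeostatic marker P2ry12 fell (2.96 to 0.789 CPM, log2 -1.47 ± 0.18). Csf1, a macrophage growth factor gene, rose (5.35 to 27.0 CPM, log2 2.24 ± 0.11). The complement gene C4b rose (7.88 to 61.8 CPM, log2 2.90 ± 0.21) and the necroptosis kinase gene Ripk1 (10.9 to 34.0 CPM, log2 1.60 ± 0.09).  Unfolded protein response genes rose by less (13 higher, 1 lower, 9 not past, 13 and 1 adjusted over the list alone). The median, 0.25, had adjusted p = 0.00265, but adjusted p = 0.437 with an estimated correlation. Pros1 and its receptor gene Axl, of phagocytic uptake, rose (9.14 to 36.2 CPM, log2 1.94 ± 0.08) and (16.1 to 61.9 CPM, log2 1.90 ± 0.11).

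Between 1d and NB 8719 of 16926 genes passed the test, 4057 higher and 4662 lower. Of these, 980 changed by at least 2-fold (9620 genes had an unadjusted p under 0.05). In the authors' deposited table, 1839 genes passed once p was adjusted, 1839 of which passed here in the same direction. Scaled to library totals, 74.3% of called genes were higher in place of 46.5%, the median log2 change of all genes then being 0.15. The oxidative phosphorylation list was lower with the authors' scaling (0 higher, 11 lower, 17 not past, 0 and 10 adjusted over the list alone). At median -0.11 the list had adjusted p = 0.00877 (adjusted p = 0.558 with an estimated correlation). It was not called without 1d 3 (adjusted p = 0.0562). With the 4 NB libraries of the same set 6950 genes passed. Here 17 gene lists were called, of which 1 lost the call when at least 1 library was left out, and NRF2 antioxidant and endothelial genes lost it within the set (adjusted p = 0.0593 and 0.0539).

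At 3d phagocyte, complement and glial transcripts were higher in retina than in NB (n = 4 against n = 6 NB). Serpina3n was still raised, from 7.09 ± 2.98 to 174 ± 21.7 CPM (log2 fold change 4.61 ± 0.22, adjusted p = 4.16e-11). Gfap, the glial filament gene, rose from 29.7 ± 2.87 to 271 ± 53.3 CPM (log2 fold change 3.16 ± 0.12, adjusted p = 2.01e-12). Mpeg1, a pore-forming protein gene of macrophages, rose from 2.92 ± 0.846 to 29.5 ± 3.91 CPM (log2 fold change 3.17 ± 0.17, adjusted p = 1.16e-10). C4b, a complement component, rose from 7.88 ± 2.32 to 74.5 ± 7.54 CPM (log2 fold change 3.2 ± 0.21, adjusted p = 1.66e-09). Also far above NB were Bcl3 (3.78 ± 0.14), Edn2 (3.76 ± 0.24), Steap4 (3.65 ± 0.21) and Acp5 (3.64 ± 0.23). Among falls, Pdc went from 2500.3 ± 259 to 1094 ± 80.3 CPM (log2 fold change -1.19 ± 0.11, adjusted p = 1.89e-07). The hexokinase gene Hk2 fell from 592 ± 108 to 259 ± 17.3 CPM (log2 fold change -1.18 ± 0.10, adjusted p = 5.13e-08). Lower too were Hdc (-2.42 ± 0.23), Glb1l3 (-2.21 ± 0.28), Chrna5 (-1.34 ± 0.17), BC065403 (-1.28 ± 0.18), Hpdl (-1.26 ± 0.18) and Dleu7 (-1.20 ± 0.18).

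Of 23 microglia and macrophage genes, 21 were higher, 0 lower and 2 not past the threshold (21 and 0 adjusted over the list alone). Their median was 1.67, adjusted p = 2.97e-18 (adjusted p = 0.0661 with an estimated correlation). Spp1, the osteopontin gene of activated phagocytes, rose from 10.3 ± 0.768 to 84.7 ± 23.0 CPM (log2 fold change 2.95 ± 0.13, adjusted p = 8.89e-12). Cd68, a lysosomal protein gene, rose (1.82 to 14.3 CPM, log2 2.69 ± 0.13). Complement genes rose (10 higher, 0 lower, 4 not past, 10 and 0 adjusted over the list alone). A median of 1.02 had adjusted p = 1.13e-05, but adjusted p = 0.133 with an estimated correlation. C1qa, of the classical pathway, rose (3.74 to 18.0 CPM, log2 2.14 ± 0.14). Phagocytosis and lysosome genes rose (18 higher, 1 lower, 5 not past, 19 and 1 adjusted over the list alone). The median, 0.42, had adjusted p = 3.39e-08, but adjusted p = 0.236 with an estimated correlation. Interferon and antigen presentation genes rose as well (27 higher, 0 lower, 1 not past, 27 and 0 adjusted over the list alone). At median 1.47 the list had adjusted p = 3.54e-16 (adjusted p = 0.286 with an estimated correlation). B2m, the class I light chain gene, rose (17.7 to 65.1 CPM, log2 1.83 ± 0.15). Resting Muller glia markers were higher (13 higher, 1 lower, 3 not past, 13 and 1 adjusted over the list alone). Their median was 0.57, adjusted p = 6.33e-08 (adjusted p = 0.133 with an estimated correlation). Crym (44.8 to 221 CPM, log2 2.30 ± 0.13), Aqp4 (135 to 228 CPM, log2 0.75 ± 0.06) and Prdx6 (136 to 234 CPM, log2 0.78 ± 0.05), expressed by these glia, rose. Extracellular matrix genes rose (14 higher, 0 lower, 6 not past, 14 and 0 adjusted over the list alone). A median of 0.52 had adjusted p = 4.07e-06, but adjusted p = 0.133 with an estimated correlation. Cell cycle genes rose (10 higher, 1 lower, 7 not past, 10 and 1 adjusted over the list alone). The median, 0.33, had adjusted p = 0.00705, but adjusted p = 0.310 with an estimated correlation. Mki67, a proliferation marker, rose (0.779 to 4.24 CPM, log2 2.00 ± 0.39).

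The rod list counted 0 higher, 29 lower and 1 not past of 30 (0 and 29 adjusted over the list alone). Their median was -0.81, adjusted p = 5.24e-15 (adjusted p = 0.364 with an estimated correlation). Slc24a1, the rod exchanger gene, fell from 1816 ± 85.9 to 946 ± 47.8 CPM (log2 fold change -0.94 ± 0.09, adjusted p = 2.97e-07). Gngt1 fell (1019 to 546 CPM, log2 -0.89 ± 0.09). Bipolar cell genes were higher by a small amount (8 higher, 0 lower, 5 not past, 8 and 0 adjusted over the list alone). Their median was 0.18, adjusted p = 0.00144 (adjusted p = 0.364 with an estimated correlation). Amacrine, horizontal and ganglion cell genes did likewise (15 higher, 1 lower, 4 not past, 16 and 1 adjusted over the list alone). A median of 0.22 had adjusted p = 1.01e-04, but adjusted p = 0.364 with an estimated correlation. Endothelial genes rose (10 higher, 0 lower, 6 not past, 12 and 0 adjusted over the list alone). The median, 0.32, had adjusted p = 2.77e-05, but adjusted p = 0.135 with an estimated correlation. Kdr, a VEGF receptor gene, rose (250.0 to 494 CPM, log2 0.98 ± 0.05). AMD risk locus genes rose (14 higher, 1 lower, 10 not past, 14 and 1 adjusted over the list alone). At median 0.30 the list had adjusted p = 3.76e-04 (adjusted p = 0.364 with an estimated correlation). Apoe, a lipid carrier gene, rose (524 to 915 CPM, log2 0.81 ± 0.10). The NRF2 antioxidant list was higher (9 higher, 1 lower, 9 not past, 10 and 1 adjusted over the list alone). Their median was 0.19, adjusted p = 0.00744 (adjusted p = 0.437 with an estimated correlation). Among DNA methylation genes Tet3 fell (331 to 214 CPM, log2 -0.63 ± 0.08) and Uhrf1 rose (0.391 to 2.15 CPM, log2 1.54 ± 0.22).

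For 3d against NB 7316 of 16926 genes passed the test, 3265 higher and 4051 lower. Of these, 379 changed by at least 2-fold (8532 genes had an unadjusted p under 0.05). In the authors' deposited table, 712 genes passed once p was adjusted, 712 of which passed here in the same direction. With library totals 77.0% of called genes were higher in place of 44.6%, the median log2 change of all genes being 0.12. Within the shallower set 6501 genes passed. In this contrast 21 gene lists were called, of which 2 (chromatin, fibroblast and pericyte) lost the call when at least 1 library was left out.

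From 6h to 1d the raised genes of the retina changed (n = 3 and n = 4). Prss56 rose from 8.28 ± 1.49 to 357 ± 117 CPM (log2 fold change 5.30 ± 0.22, adjusted p = 6.67e-12). Edn2 rose from 5.82 ± 1.60 to 81.4 ± 14.1 CPM (log2 fold change 3.71 ± 0.28, adjusted p = 6.92e-09). Others that rose were Tnnt2 (4.26 ± 0.21), CT025671.4 (4.2 ± 0.16) and Cdsn (3.75 ± 0.20). Nt5e, an ectonucleotidase gene of rods, fell from 349 ± 22.1 to 73.0 ± 17.0 CPM (log2 fold change -2.28 ± 0.12, adjusted p = 5.74e-11). So did Kcnj13 (-2.04 ± 0.25), Arg2 (-1.96 ± 0.16) and Glb1l3 (-2.35 ± 0.33). Interferon genes rose further (26 of 28 higher, 1 lower). A median of 1.4 had adjusted p = 8.60e-15, but adjusted p = 0.415 with an estimated correlation. Rod genes fell (0 of 30 higher, 27 lower). Their median was -0.66, adjusted p = 7.17e-12, but adjusted p = 0.509 with an estimated correlation. The RPE identity list was lower (2 of 24 higher, 9 lower). A median of -0.21 had adjusted p = 0.0145, but adjusted p = 0.753 with an estimated correlation. Mitochondrially encoded genes were lower (0 of 13 higher, 7 lower). Their median was -0.27, adjusted p = 0.00880, but adjusted p = 0.753 with an estimated correlation. In all 5932 of 16926 genes passed the test, 2963 higher and 2969 lower. Of these, 528 changed by at least 2-fold (7402 genes had an unadjusted p under 0.05). This contrast crosses the deeper and shallower sets. With a set term 2427 genes passed, and the called fall of Etnppl (-1.93 ± 0.42) became -0.14 ± 0.32, adjusted p = 0.832. Scaled to library totals, 75.3% of called genes were higher in place of 50.0%, the median log2 change of all genes being 0.13.

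From 1d to 3d rod transcripts rose in the retina (23 of 30 higher, 0 lower). A median of 0.46 had adjusted p = 1.37e-11, but adjusted p = 0.509 with an estimated correlation. Both groups had n = 4. Glul rose from 629 ± 35.6 to 2703 ± 154 CPM (log2 fold change 2.10 ± 0.07, adjusted p = 4.88e-14). Prss56 fell from 357 ± 117 to 2.35 ± 0.722 CPM (log2 fold change -6.95 ± 0.21, adjusted p = 3.93e-14). Acp5, a phosphatase gene of phagocytes, rose from 0.174 ± 0.188 to 7.59 ± 2.16 CPM (log2 fold change 3.59 ± 0.25, adjusted p = 5.61e-09). Also higher were BC055402 (2.66 ± 0.09), Mki67 (2.35 ± 0.43) and Adgre1 (2.10 ± 0.27). Lower were Cdsn (-3.29 ± 0.18), CT025671.4 (-2.84 ± 0.15), Tnnt2 (-2.61 ± 0.20) and Lad1 (-2.51 ± 0.20). Microglial genes rose (20 of 23 higher, 1 lower). Their median was 1.26, adjusted p = 3.48e-17, but adjusted p = 0.122 with an estimated correlation. Glial reactivity genes fell (0 of 23 higher, 20 lower). A median of -0.95 had adjusted p = 5.02e-16, but adjusted p = 0.180 with an estimated correlation. Together 3626 of 16926 genes passed the test, 1657 higher and 1969 lower. Of these, 334 changed by at least 2-fold (5584 genes had an unadjusted p under 0.05).

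The RPE libraries held transcripts of neighbouring cells. Rpe65, the isomerase gene of the visual cycle, averaged 2462 ± 797 CPM in NB RPE (SD, n = 5). Relative to the retina of the same group, whose table was normalized separately, rod genes stood at 5.85 to 8.62% in NB, 11.6 to 34.5% at 6h, 10.7 to 31.7% at 1d and 13.1 to 21.7% at 3d. Krt5, a keratin gene of surface epithelium, averaged 10250.3 ± 3169.7 CPM in NB. Surface epithelial markers made up from 1.94% of CPM in 3d library 2 to 7.55% in 1d library 4, with 6.47% in NB B3, and these 3 libraries and NB A1 stood apart on the first principal component. The median log2 change of these markers was -0.11 at 6h, 0.14 at 1d and -0.64 at 3d (adjusted p = 5.83e-05 at 3d, but adjusted p = 0.946 with an estimated correlation). At no time did limma call any of the 18 (2, 2 and 6 at an unadjusted p under 0.05).

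At 6h a few RPE transcripts were lower in RPE than in NB (n = 3 against n = 5), in calls that hung on single libraries. Osmr rose from 105 ± 11.1 to 277 ± 27.4 CPM (log2 fold change 1.39 ± 0.20, adjusted p = 0.00480). Cebpd rose from 12.2 ± 4.19 to 34.8 ± 4.40 CPM (log2 fold change 1.53 ± 0.24, adjusted p = 0.00981), and the signal inhibitor gene Socs3 from 8.0 ± 2.36 to 20.1 ± 3.58 CPM (log2 fold change 1.32 ± 0.23, adjusted p = 0.0154). Adra2c, an adrenergic receptor gene, fell from 74.4 ± 12.4 to 21.8 ± 4.39 CPM (log2 fold change -1.75 ± 0.26, adjusted p = 0.00657). Sostdc1, a BMP antagonist gene, fell from 82.9 ± 12.3 to 27.8 ± 7.44 CPM (log2 fold change -1.59 ± 0.22, adjusted p = 0.00380). Rpe65 fell from 2462 ± 797 to 944 ± 195 CPM (log2 fold change -1.35 ± 0.29, adjusted p = 0.0378). Muc3a, a mucin gene, rose from 0.117 ± 0.115 to 3.36 ± 0.60 CPM (log2 fold change 2.65 ± 0.25, adjusted p = 3.12e-04). Neuronal and photoreceptor genes rose as well, Ache (1.96 ± 0.23), Neurod1 (1.97 ± 0.33), Pcare (1.94 ± 0.33), Tpbgl (1.86 ± 0.25) and Gnb3 (1.74 ± 0.32), with Fam135b (1.99 ± 0.44) and Fabp4 (1.84 ± 0.36). Lower were Sfrp5 (-1.71 ± 0.29), Crhr2 (-1.42 ± 0.24), Gip (-1.35 ± 0.27) and Dusp4 (-1.27 ± 0.25).

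Among 25 RPE identity genes 0 passed the test as higher, 3 as lower and 22 did not (1 and 10 adjusted over the list alone). With a median of -0.45 the list had adjusted p = 6.96e-07, but adjusted p = 0.429 with an estimated correlation. Col8a2 (743 to 355 CPM, log2 -1.05 ± 0.21, adjusted p = 0.0279), Car14 (607 to 299 CPM, log2 -1.02 ± 0.22, adjusted p = 0.0368) and Enpp2 (1895 to 952 CPM, log2 -0.98 ± 0.22, adjusted p = 0.0401), genes of matrix, pH and lipid handling in RPE, fell. The visual cycle list was lower (0 higher, 1 lower, 11 not past, 2 and 7 adjusted over the list alone). A median of -0.64 had adjusted p = 0.00154, but adjusted p = 0.437 with an estimated correlation. The melanin synthesis list was lower (0 higher, 1 lower, 11 not past, 0 and 3 adjusted over the list alone). The median, -0.36, had adjusted p = 0.00247, but adjusted p = 0.437 with an estimated correlation. The glial reactivity list was higher (3 higher, 0 lower, 20 not past, 5 and 0 adjusted over the list alone). At median 0.41 the list had adjusted p = 9.63e-04 (adjusted p = 0.360 with an estimated correlation). Neural retina lists were higher in the same samples. Rods were among them (0 higher, 0 lower, 30 not past, 14 and 0 adjusted over the list alone). Their median was 0.81, adjusted p = 8.96e-09 (adjusted p = 0.437 with an estimated correlation). The cone list was higher (3 higher, 0 lower, 8 not past, 7 and 0 adjusted over the list alone). A median of 1.04 had adjusted p = 8.73e-08, but adjusted p = 0.200 with an estimated correlation. The bipolar list was higher (0 higher, 0 lower, 13 not past, 10 and 0 adjusted over the list alone). The median, 1.24, had adjusted p = 6.33e-06, but adjusted p = 0.408 with an estimated correlation. Of 2275 genes at least 4-fold higher in NB retina than in NB RPE, 110 were called, 110 of them higher. Without those genes in the test 60 passed, 11 higher and 49 lower. Immediate early genes were not called (0 higher, 0 lower, 18 not past, 0 and 0 adjusted over the list alone). At median -0.09 the list had adjusted p = 0.881. Compared with NB A1 alone they were called as higher. T cell genes were not called either (0 higher, 0 lower, 7 not past, 0 and 0 adjusted over the list alone). Their median was -0.25, adjusted p = 0.312.

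For RPE at 6h 244 of 16712 genes passed the test, 135 higher and 109 lower. Of these, 119 changed by at least 2-fold (3036 genes had an unadjusted p under 0.05). The count moved with single libraries, to 9 without 6h 1, 442 without 6h 2, 17 without 6h 3, 1011 without NB A1, 41 without NB B1, 40 without NB B2 and 67 without NB B4. Rpe65 had log2 -1.17 to -1.46 without 6h 1, 6h 3, NB B1, NB B2 or NB B4. Adjusted p was 0.274, 0.137, 0.0880, 0.0960 and 0.0553. NB A1 alone shares the deeper set with the 6h libraries, and against it 41 genes passed, 18 higher and 23 lower, with 6 of the 244 calls among them. That fit takes its spread from the 3 6h libraries, and 1 NB library cannot decide which calls stand. Fam135b, Neurod1, Pcare, Fabp4, Gnb3, Sfrp5, Crhr2, Gip and Dusp4 lost their calls without 6h 1 or 6h 3 (adjusted p = 0.0557 to 0.273). Fam135b, Fabp4, Gip and Dusp4 lost them also without NB B1, NB B2 or NB B4 (adjusted p = 0.0532 to 0.104), as did Gnb3 without NB B2 (adjusted p = 0.0696) and Adra2c without 6h 1 (adjusted p = 0.0746). Library totals changed the split, so that 81.0% of called genes were higher in place of 55.3%. In the authors' deposited table, 9 genes passed once p was adjusted, 9 of which passed here in the same direction. In this contrast 17 gene lists were called, of which 5 (interferon, NRF2, glycolysis, cholesterol synthesis and mitochondrially encoded) lost the call when at least 1 library was left out.

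At 1d RPE transcripts were lower than in NB (n = 4 against n = 5). Rpe65 fell from 2462 ± 797 to 432 ± 139 CPM (log2 fold change -2.51 ± 0.27, adjusted p = 4.30e-05). Serpina3n rose from 314 ± 60.0 to 4691 ± 1725 CPM (log2 fold change 3.84 ± 0.26, adjusted p = 8.59e-07). Serpine3, another serpin gene, rose from 3.51 ± 0.889 to 79.0 ± 20.9 CPM (log2 fold change 4.30 ± 0.32, adjusted p = 1.67e-06). Chil1, which codes for a chitinase-like secreted protein, rose from 109.5 ± 26.9 to 1089.6 ± 342 CPM (log2 fold change 3.29 ± 0.24, adjusted p = 1.67e-06). Lcn2, an iron-binding protein gene, rose from 3.70 ± 2.16 to 37.4 ± 15.4 CPM (log2 fold change 3.25 ± 0.36, adjusted p = 5.30e-05). Higher too were Prss56 (4.15 ± 0.39), Lalba (3.4 ± 0.22), Crym (3.18 ± 0.36) and Gnb3 (3.06 ± 0.29). Inpp5k, a phosphoinositide phosphatase gene, fell from 836 ± 217 to 150.4 ± 43.2 CPM (log2 fold change -2.48 ± 0.21, adjusted p = 5.82e-06). The thyrotropin receptor gene Tshr fell from 126 ± 44.3 to 26.2 ± 5.51 CPM (log2 fold change -2.21 ± 0.23, adjusted p = 3.84e-05). Other falls included Gpr139 (-2.48 ± 0.31), Fam243 (-2.41 ± 0.34), AC154492.1 (-2.39 ± 0.23), Trhde (-2.39 ± 0.32) and Minar1 (-2.23 ± 0.23).

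Among 12 visual cycle genes 1 passed the test as higher, 7 as lower and 4 did not (2 and 8 adjusted over the list alone). With a median of -0.84 the list had adjusted p = 2.59e-05, but adjusted p = 0.364 with an estimated correlation. Rdh10 (809.8 to 357 CPM, log2 -1.17 ± 0.20, adjusted p = 0.00226) and Rdh11 (58.4 to 33.5 CPM, log2 -0.77 ± 0.14, adjusted p = 0.00288), retinol dehydrogenase genes, fell. The RPE identity list was lower (1 higher, 10 lower, 14 not past, 2 and 16 adjusted over the list alone). The median, -0.72, had adjusted p = 6.33e-08, but adjusted p = 0.402 with an estimated correlation. The lipid enzyme gene Enpp2 fell from 1895 ± 499 to 545 ± 72.2 CPM (log2 fold change -1.77 ± 0.20, adjusted p = 7.22e-05). The integrin gene Itgb8 fell from 684 ± 242 to 157 ± 36.9 CPM (log2 fold change -2.09 ± 0.25, adjusted p = 1.05e-04). The melanin synthesis list was lower (0 higher, 5 lower, 7 not past, 0 and 7 adjusted over the list alone). At median -0.63 the list had adjusted p = 1.85e-04 (adjusted p = 0.402 with an estimated correlation). Oca2 (122 to 55.0 CPM, log2 -1.12 ± 0.17, adjusted p = 8.21e-04) and Rab27a (306 to 193 CPM, log2 -0.67 ± 0.11, adjusted p = 0.00115), of melanosome pH and transport, fell. Mertk, the receptor gene for outer segment uptake, fell (70.9 to 31.1 CPM, log2 -1.12 ± 0.22, adjusted p = 0.00551). Nqo1, a quinone reductase gene, fell (104 to 49.2 CPM, log2 -1.07 ± 0.11, adjusted p = 3.57e-05). The AMD risk locus list was lower (2 higher, 7 lower, 18 not past, 2 and 11 adjusted over the list alone). Their median was -0.33, adjusted p = 0.00235 (adjusted p = 0.437 with an estimated correlation). The growth factor gene Vegfa fell (287 to 102 CPM, log2 -1.44 ± 0.21, adjusted p = 7.27e-04). The endothelial list was lower (1 higher, 4 lower, 11 not past, 1 and 8 adjusted over the list alone). A median of -0.63 had adjusted p = 6.46e-04, but adjusted p = 0.437 with an estimated correlation. Csf1r, the macrophage growth factor receptor gene, fell (214 to 73.7 CPM, log2 -1.53 ± 0.19, adjusted p = 1.52e-04).

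The glial reactivity list counted 10 higher, 0 lower and 13 not past of 23 (18 and 0 adjusted over the list alone). Their median was 0.75, adjusted p = 5.33e-17 (adjusted p = 0.0579 with an estimated correlation). Osmr rose from 105 ± 11.1 to 615 ± 179 CPM (log2 fold change 2.50 ± 0.18, adjusted p = 1.67e-06). A2m rose from 247 ± 42.8 to 1526 ± 384 CPM (log2 fold change 2.61 ± 0.21, adjusted p = 4.38e-06) and Socs3 (8.0 to 39.1 CPM, log2 2.26 ± 0.21, adjusted p = 1.51e-05). Cfi (1.31 to 13.1 CPM, log2 2.83 ± 0.33, adjusted p = 7.94e-05), C4b (47.7 to 217 CPM, log2 2.30 ± 0.30, adjusted p = 2.38e-04) and C3 (6.78 to 18.5 CPM, log2 1.35 ± 0.26, adjusted p = 0.00609), complement genes, rose. Their list was called as higher (3 higher, 1 lower, 11 not past, 6 and 2 adjusted over the list alone). At median 0.17 the list had adjusted p = 0.0284 (adjusted p = 0.437 with an estimated correlation). They were not called without NB B3 (adjusted p = 0.150), without 1d 1 (adjusted p = 0.0579) and without 1d 3 (adjusted p = 0.0517). Timp1, a metalloproteinase inhibitor gene, rose (2.92 to 21.5 CPM, log2 2.67 ± 0.28, adjusted p = 3.34e-05). The cone list was higher (4 higher, 0 lower, 7 not past, 5 and 0 adjusted over the list alone). Their median was 0.81, adjusted p = 7.83e-04 (adjusted p = 0.402 with an estimated correlation). Rod genes were not called (0 higher, 0 lower, 30 not past, 0 and 0 adjusted over the list alone). A median of 0.13 had adjusted p = 0.580. They were called as higher without 1d 4 (adjusted p = 0.0117). Retina carried over at the rod share would hold up to 133 CPM of Crym, 304 of Gnb3 and 113 of Prss56, and the rises of these genes lay within it. Serpina3n (bound 124 CPM), Serpine3 (2.15), Chil1 (39.6), Osmr (31.9) and A2m (71.2) exceeded it in every 1d library.

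In RPE at 1d 937 of 16712 genes passed the test, 296 higher and 641 lower. Of these, 370 changed by at least 2-fold (3613 genes had an unadjusted p under 0.05). Among the called genes 114 were at least 4-fold higher in NB retina than in NB RPE, 98 rising and 16 falling. The count was 618 without NB B2 and 1426 without NB B3, and 452 against the 4 NB libraries of the same set, where Rpe65 had log2 -2.34 ± 0.23, adjusted p = 0.00114 and Serpina3n 3.92 ± 0.27, adjusted p = 3.53e-04. In the authors' deposited table, 216 genes passed once p was adjusted, 216 of which passed here in the same direction. In this contrast 11 gene lists were called, of which 4 (complement, unfolded protein response, cell cycle and amacrine, horizontal and ganglion cell) lost the call when at least 1 library was left out.

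Few RPE genes still differed from NB at 3d (n = 4 against n = 5 NB). Serpine3 rose from 3.51 ± 0.889 to 119 ± 35.7 CPM (log2 fold change 4.87 ± 0.32, adjusted p = 1.26e-06). Serpina3n rose from 314 ± 60.0 to 1812 ± 588 CPM (log2 fold change 2.50 ± 0.26, adjusted p = 1.90e-04). Cfi rose from 1.31 ± 0.536 to 18.3 ± 6.10 CPM (log2 fold change 3.36 ± 0.33, adjusted p = 1.31e-04). C4b rose from 47.7 ± 24.0 to 231 ± 66.9 CPM (log2 fold change 2.36 ± 0.30, adjusted p = 0.00205). Lalba, a milk-protein gene, rose from 1.44 ± 0.276 to 16.4 ± 6.03 CPM (log2 fold change 3.07 ± 0.22, adjusted p = 1.90e-06). Gnb3, a cone transducin gene, rose from 18.0 ± 3.11 to 80.4 ± 17.6 CPM (log2 fold change 2.12 ± 0.29, adjusted p = 0.00354). Phagocyte genes were higher, Spp1 (10.9 to 39.1 CPM, log2 1.89 ± 0.30, adjusted p = 0.0141) and Mmp12 (0.501 to 3.27 CPM, log2 1.93 ± 0.28, adjusted p = 0.00644) of activated cells. So were the receptor and complement genes Tyrobp (3.38 to 8.08 CPM, log2 1.14 ± 0.18, adjusted p = 0.0141), C1qb (8.79 to 17.1 CPM, log2 0.95 ± 0.18, adjusted p = 0.0374) and C3ar1 (0.824 to 3.18 CPM, log2 1.50 ± 0.19, adjusted p = 0.00205). Rgcc, a cell cycle regulator gene, and Mfsd2a, a lipid transporter gene, fell (9.07 to 2.63 CPM, log2 -1.55 ± 0.28, adjusted p = 0.0309) and (32.2 to 20.0 CPM, log2 -0.69 ± 0.12, adjusted p = 0.0249). Within the shallower set C4b had log2 2.28 ± 0.37, adjusted p = 0.0926, Spp1 1.96 ± 0.37, adjusted p = 0.123, Rgcc -1.34 ± 0.28, adjusted p = 0.153 and Mfsd2a -0.64 ± 0.14, adjusted p = 0.154. Spp1 lost its call without NB B1, 3d 1 or 3d 3 (adjusted p = 0.0540 to 0.0814). Rgcc lost it without NB A1, NB B1, NB B2, 3d 1, 3d 2 or 3d 4 (adjusted p = 0.0536 to 0.158), and Mfsd2a without NB A1, NB B1, NB B3, 3d 1, 3d 3 or 3d 4 (adjusted p = 0.0547 to 0.0934).

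Among 23 microglia and macrophage genes 4 passed the test as higher, 0 as lower and 19 did not (11 and 0 adjusted over the list alone). With a median of 0.50 the list had adjusted p = 1.12e-08, but adjusted p = 0.191 with an estimated correlation. The complement list was higher (3 higher, 0 lower, 12 not past, 7 and 1 adjusted over the list alone). At median 0.36 the list had adjusted p = 2.17e-08 (adjusted p = 0.0985 with an estimated correlation). The glial reactivity list was higher (2 higher, 0 lower, 21 not past, 6 and 1 adjusted over the list alone). Their median was 0.39, adjusted p = 2.96e-06 (adjusted p = 0.161 with an estimated correlation). A2m rose (247 to 807 CPM, log2 1.68 ± 0.21, adjusted p = 0.00205). The red blood cell list was higher (0 higher, 0 lower, 5 not past, 4 and 0 adjusted over the list alone). A median of 1.16 had adjusted p = 2.50e-06, but adjusted p = 0.235 with an estimated correlation. The lens list was likewise higher with 0 members called (0 higher, 0 lower, 18 not past, 0 and 0 adjusted over the list alone). The median, 0.98, had adjusted p = 1.95e-05, but adjusted p = 0.478 with an estimated correlation. Visual cycle genes were not called (0 higher, 0 lower, 12 not past, 0 and 0 adjusted over the list alone). At median 0.01 the list had adjusted p = 0.959. Their mean was -0.002, and they were called as lower without 3d 2 (adjusted p = 0.0476). RPE identity genes were not called (0 higher, 0 lower, 25 not past, 0 and 1 adjusted over the list alone). Their median was 0.11, adjusted p = 0.454. Without NB B3, 1d 4 and 3d 2 their median was -0.17, adjusted p = 0.00103.

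In the 3d RPE 30 of 16712 genes passed the test, 27 higher and 3 lower. Of these, 26 changed by at least 2-fold (1659 genes had an unadjusted p under 0.05). The count was 15 without NB B1, 18 without NB B3 and 16 without 3d 1, and 13 within the shallower set, so that not all of the 30 calls can stand without NB B1, NB B3 or 3d 1. In the authors' deposited table, 13 genes passed once p was adjusted, 13 of which passed here in the same direction. In this contrast 20 gene lists were called, of which 8 lost the call when at least 1 library was left out, among them the lists for melanin synthesis, rods, AMD risk loci and cell death.

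From 6h to 1d in RPE, Serpina3n rose from 332 ± 51.0 to 4691 ± 1725 CPM (log2 fold change 3.75 ± 0.29, adjusted p = 1.20e-05) with n = 3 and n = 4. Chil1 rose from 94.0 ± 10.2 to 1089.6 ± 342 CPM (log2 fold change 3.48 ± 0.28, adjusted p = 1.20e-05). Others that rose were Serpine3 (4.27 ± 0.36), Prss56 (3.59 ± 0.44) and Mmp3 (2.93 ± 0.43). Inpp5k fell from 645 ± 116 to 150.4 ± 43.2 CPM (log2 fold change -2.12 ± 0.24, adjusted p = 3.63e-04). Lower too were Tpbgl (-2.05 ± 0.26), Ppef2 (-1.88 ± 0.32), Unc13c (-2.42 ± 0.59) and Slc6a20b (-1.75 ± 0.42). Ppef2 lost its call without 6h 1 or 6h 3 (adjusted p = 0.0612 to 0.0761), and Unc13c and Slc6a20b without 6h 1, 6h 2, 6h 3, 1d 2 or 1d 4 (adjusted p = 0.0705 to 0.163). The glial reactivity list was higher (8 of 23 genes higher, 0 lower). A median of 0.56 had adjusted p = 2.30e-08, but adjusted p = 0.180 with an estimated correlation. The rod list was lower (0 of 30 higher, 3 lower). Their median was -0.61, adjusted p = 1.20e-05, but adjusted p = 0.753 with an estimated correlation. Endothelial, bipolar and mitochondrially encoded lists were lower, with 0 members called by limma (medians -0.47, -0.62 and -0.34, adjusted p = 0.00404, 0.0110 and 0.00880, none passing with an estimated correlation). In all 567 of 16712 genes passed the test, 295 higher and 272 lower. Of these, 171 changed by at least 2-fold (3973 genes had an unadjusted p under 0.05). This contrast crosses the sets, and with a set term, which rests on NB A1 alone, 4 genes passed. Slc6a20b stood there at log2 -0.08 ± 0.55, Serpine3 at 3.71 ± 0.64, adjusted p = 0.0979 and Inpp5k at -1.41 ± 0.37, adjusted p = 0.729. Prss56 (3.4 ± 0.81), Mmp3 (2.93 ± 0.79), Unc13c (-2.20 ± 1.08), Tpbgl (-1.45 ± 0.43) and Ppef2 (-1.17 ± 0.55) lost their calls too, with wider errors (lowest adjusted p = 0.548). Single libraries moved the count to 66 without 6h 1, 184 without 6h 2, 46 without 6h 3, 176 without 1d 2 and 121 without 1d 4. Scaled to library totals, 37.1% of called genes were higher in place of 52.0%, the median log2 change of all genes being -0.12.

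RPE transcripts were higher at 3d than at 1d (n = 4 and n = 4). Rpe65 rose from 432 ± 139 to 1960.2 ± 582 CPM (log2 fold change 2.19 ± 0.28, adjusted p = 7.91e-04). Itgb8 rose from 157 ± 36.9 to 735 ± 202 CPM (log2 fold change 2.22 ± 0.26, adjusted p = 4.23e-04). Inpp5k rose from 150.4 ± 43.2 to 766 ± 183 CPM (log2 fold change 2.35 ± 0.22, adjusted p = 2.46e-04). Others were Trhde (2.47 ± 0.34) and Fam243 (2.33 ± 0.35). Lcn2 fell from 37.4 ± 15.4 to 4.77 ± 1.90 CPM (log2 fold change -2.82 ± 0.38, adjusted p = 9.34e-04). So did Prss56 (-4.03 ± 0.41), Mmp3 (-2.43 ± 0.40), Prph (-2.38 ± 0.26) and Muc3a (-2.38 ± 0.25). Visual cycle genes rose (7 of 12 higher, 0 lower). A median of 0.90 had adjusted p = 1.53e-04, but adjusted p = 0.49 with an estimated correlation. The RPE identity list was higher (11 of 25 higher, 1 lower). Their median was 0.79, adjusted p = 1.35e-07, but adjusted p = 0.49 with an estimated correlation. The microglial list was higher (10 of 23 higher, 0 lower). A median of 0.70 had adjusted p = 4.06e-06, but adjusted p = 0.415 with an estimated correlation. The glial reactivity list was lower (0 of 23 genes higher, 9 lower). Their median was -0.77, adjusted p = 7.33e-08, but adjusted p = 0.180 with an estimated correlation. The lens list was higher (0 of 18 higher, 0 lower). A median of 1.09 had adjusted p = 0.00263, but adjusted p = 0.753 with an estimated correlation. Limma called 0 of 18 surface epithelium markers, and their list was lower by a median of -0.72 (adjusted p = 5.83e-05, but adjusted p = 0.946 with an estimated correlation). Here 1100 of 16712 genes passed the test, 823 higher and 277 lower. Of these, 378 changed by at least 2-fold (4775 genes had an unadjusted p under 0.05). The count was 447 without 1d 4, 363 without 3d 2 and 598 without 3d 4.

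The retina and RPE responses, each against its own NB libraries, were compared (log2 fold change in retina, then in RPE). Carried-over retina in the RPE libraries could give part of these differences. At 6h the retina rose more in Lif (5.34 and 0.44), Fosl1 (5.38 and 0.93) and Icam1 (3.68 and -0.05). At 1d it did so in Nlrc5 (4.60 and 0.09), Lad1 (4.98 and 0.52) and Bcl3 (4.99 and 0.78), and at 3d in Steap4 (3.65 and -1.02), Bcl3 (3.78 and -0.47) and Acp5 (3.64 and -0.51). RPE lay above retina for Muc3a (0.37 and 2.65) at 6h, Aqp1 (-1.75 and 0.49) and Npl (0.33 and 2.56) at 1d, and Serpine3 (3.15 and 4.87) and Cfi (1.95 and 3.36) at 3d. The last 2 differences were lost with a pseudocount of 0.1 (adjusted p = 0.656 and 0.247). Glial reactivity genes rose more in retina on the log2 scale at 6h, 1d and 3d (14, 17 and 16 of 23 above, 0 below). The median differences were 1.57, 1.60 and 1.37 (adjusted p = 2.36e-16, 1.28e-15 and 6.17e-20). With an estimated correlation adjusted p was 0.00570, 0.00580 and 0.00442. Microglial genes did so at 3d (17 above, 0 below of 22). The median difference was 1.31 (adjusted p = 1.16e-19, or 0.00570 with an estimated correlation). Serpina3n, A2m and Osmr were higher in NB RPE than NB retina and gained more CPM in RPE at 1d. Gfap and Socs3 gained more in retina. Of 15105 genes the difference passed for 2653 at 6h, 3284 at 1d and 1842 at 3d. Scaled to library totals, 82.9% of them lay above at 1d in place of 55.6%, and 78.0% at 3d in place of 48.6%. The 6h count was 1738 without Retina 6h 3 and 1536 without RPE 6h 3, and the 3d count 3273 without RPE NB A1. Genes at least 2-fold higher in both tissues numbered 8 at 6h, 55 at 1d and 16 at 3d, where independent calls would give 1.49, 4.48 and 0.416, an excess that carried-over retina would also give. Of all calls, 14 were lower in both at 6h (expected 19.0) and 123 opposite at 1d.

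**Figure D1:**
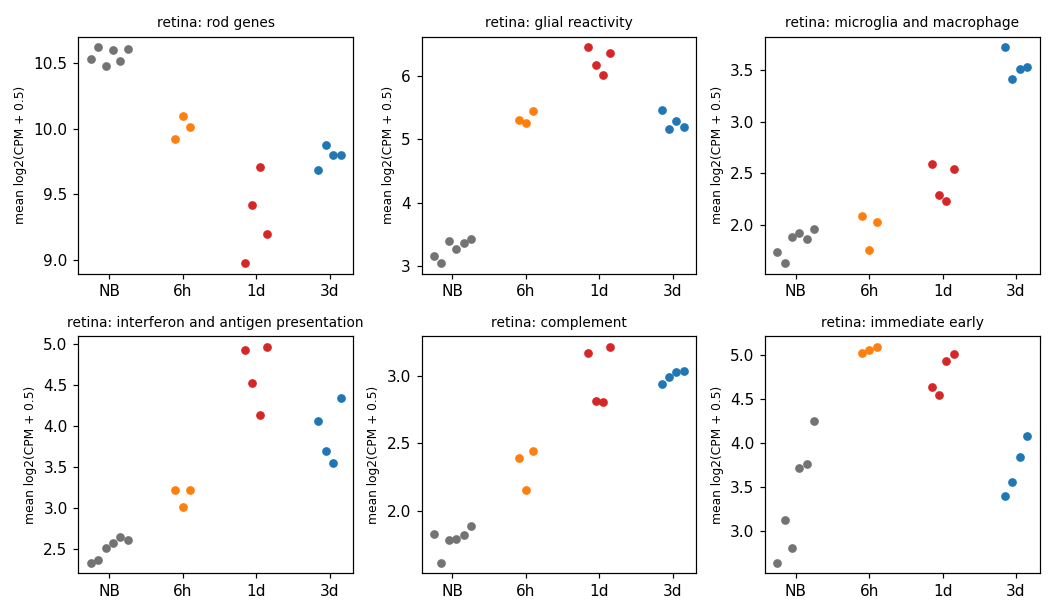
Mean log2(CPM + 0.5) of 6 gene lists in each retina library, by group (NB n = 6, 6h n = 3, 1d n = 4, 3d n = 4).

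**Figure D2:**
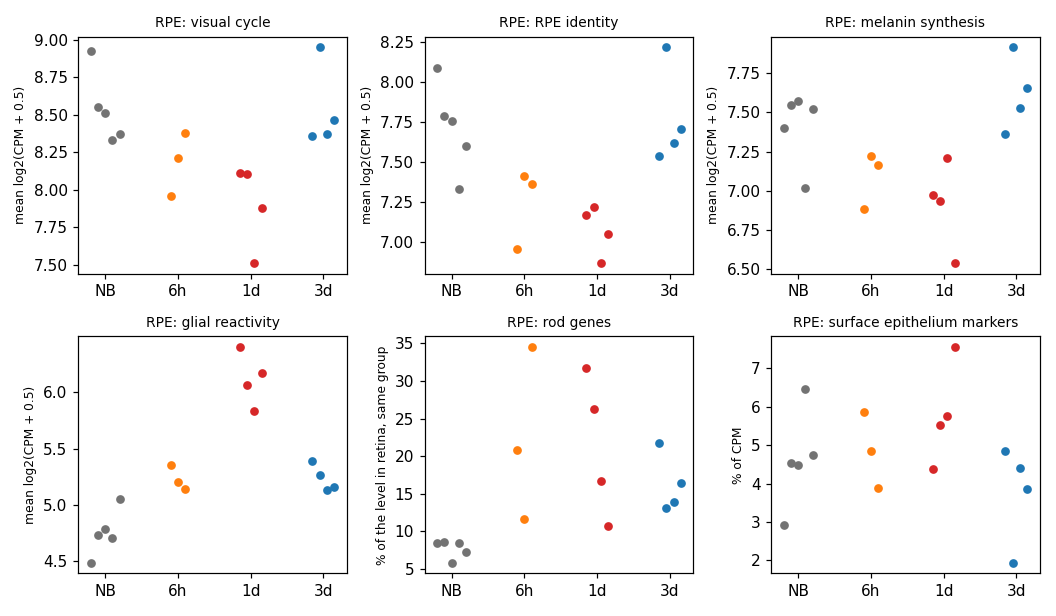
Mean log2(CPM + 0.5) of 4 gene lists in each RPE library, with rod genes as a percentage of their level in the retina of the same group and surface epithelium markers as a percentage of CPM, by group (NB n = 5, 6h n = 3, 1d n = 4, 3d n = 4).

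**Figure D3:**
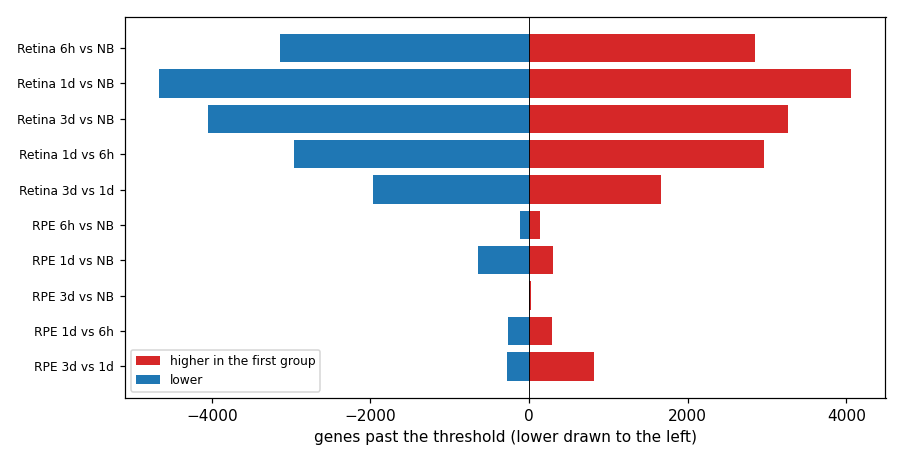
Genes higher and lower past the threshold (limma, adjusted p under 0.05) in each contrast of groups within a tissue.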

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

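All tests of the origin of RPE and rod patterns given here, except the slope and the within-set median at 6h, were chosen after the results were seen, and so were the surface markers; the splits of libraries were planned.

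The retina and RPE responses to the same times differed, tested as a difference of their changes against NB. The difference passed for 2653 genes at 6h, 3284 at 1d and 1842 at 3d. Positive values here mean a higher log2 change in retina. At 6h they were Lif 4.90, Fosl1 4.45, Tnfrsf12a 3.82, Bcl3 3.75 and Icam1 3.73, against Muc3a -2.28, Mir124a-1hg -2.14, Fabp4 -2.14, Ube4bos1 -2.13 and BC065403 -2.10. At 1d they were Nlrc5 4.51, Lad1 4.47, Bcl3 4.21, Endou 4.07 and Steap4 3.81, against Egfl6 -2.30, Aqp1 -2.24, Npl -2.24 and Crxos -2.18. At 3d they were Steap4 4.67, Bcl3 4.25, Acp5 4.15, Oasl2 2.86 and Nlrc5 2.82, against Serpine3 -1.73, Aqp1 -1.51, Cfi -1.42, Gnb3 -1.38 and Lrrc23 -1.37. Glial reactivity genes lay higher in retina by medians of 1.57 at 6h, 1.60 at 1d and 1.37 at 3d, and microglial genes by 1.31 at 3d, with both correlations of the list test. The 3d differences of Serpine3 and Cfi were lost with a pseudocount of 0.1, and the 6h differences of Mir124a-1hg and BC065403 with a set term (-1.50 and -1.98, adjusted p = 0.243 and 0.0547).

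Within groups of at least 4 libraries, 19 of 324 sets of values held 1 library set apart by a gap that was a large part of the group's range, where chance gives about 1 in 20. The ratio of gap to range in retina was 0.881 for Crym, 0.880 for Spp1 and 0.866 for Aqp4, all high in 3d library 1, 0.846 for Fgf2 (low in 1d 3), 0.633 for Cnga1 (high in NB A2) and 0.650 for Hmox1 (low in NB B1). In RPE, NB A1 was high for Gpr139 (0.734), Inpp5k (0.766), Rdh11 (0.760) and Trhde (0.722) and for reads per library (0.862), being the deeper NB library there. Other RPE values were 0.955 for A2m and 0.835 for Abca4 (high in 3d 2), 0.948 for C3ar1 (high in 3d 1), 0.847 for Mmp12 (high in 3d 3), 0.838 for Socs3 (high in 1d 1), 0.838 for Vegfa (low in 1d 4), 0.720 for Cfi (high in NB B4) and 0.769 for Rdh8 (high in NB B1). No library was left out for these values.

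Neural retina transcripts were higher in 6h RPE than in NB RPE, with a median log2 change of 0.99 over 639 genes at least 16-fold higher in NB retina than in NB RPE. If carried-over retina were the source, their RPE change might follow the retina's own change, and its slope was 0.36 ± 0.03, between the limits set for either answer. Against the NB library of the deeper set the median was 0.83, over that 1 library. Carry-over and the set difference cannot be told apart from a change in RPE cells here, because the slope met neither limit and a single NB library shares the set.

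Of 137 genes at least 2-fold higher in RPE at 1d, 14 had no retina value and were not tested, and 35 exceeded in every 1d library what carried-over retina at the highest rod share would hold, Serpina3n, Osmr and Chil1 among them, which argues against carry-over as their whole source. Of the other 88, 84 were higher in NB retina than in NB RPE, and the median correlation of their levels with the rod share of the 4 libraries was 0.86. The bound favours genes of both kinds, so carry-over and other sources cannot be told apart for them. Without NB B3, 1d 4 and 3d 2, 120 of the 137 stayed past the threshold, and 99 without NB A1 as well, which leaves a part in these libraries open. Surface markers went both ways at 1d (median 0.14, Krt12 2155 to 7828 CPM, Krt7 1038 to 867), leaving that tissue open. A response of RPE cells, of choroidal or immune cells in the preparation, or of mice differing in severity stays open for the 35, and so does an unequal share of the sexes, which was not tested.

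Rod transcripts were higher in retina at 3d than at 1d in 23 of 30 genes, also under library totals and median ratios. These scalings differed little here, so scaling stays open. A lower share of all other cells would lower their lists, but 3 of 5 other cell-type lists had most of their members higher at 3d. The mean rod level of 1 1d library (library 3, 9.71 log2) lay above the lowest 3d library (library 1, 9.69), so that mice of differing severity could also give the pattern, and recovery within an animal was not measured.

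The groups were also split in other ways, at most 100 per comparison, and splits with as many calls were counted, the real one included. In retina these were 1 of 84 (highest other 147) at 6h, 1 of 100 (highest other 4261) at 1d, 1 of 100 (highest other 2714) at 3d, 1 of 35 (highest other 4609) for 1d against 6h and 1 of 35 (highest other 539) for 3d against 1d. In RPE they were 1 of 56 (highest other 3) at 6h, 2 of 100 (highest other 1270) at 1d, 1 of 100 (highest other 5) at 3d, 1 of 35 (highest other 402) and 1 of 35 (highest other 1) for the contrasts of times. For the tissue difference they were 2 of 100 (highest other 2700) at 6h, 1 of 100 (highest other 2535) at 1d and 2 of 100 (highest other 2702) at 3d. The real values were 5991, 8719, 7316, 5932 and 3626 in retina and 244, 937, 30, 567 and 1100 in RPE. For the difference they were 2653, 3284 and 1842. Each share of splits was under 0.05, unadjusted. In RPE at 1d the split of NB A1, B1, B2 and B4 from the rest gave 1270 genes, more than the real 937, which points to a structure of the samples in which NB B3 lies with the 1d libraries; without NB B3 the real count was 1426. Tissue splits with more calls (6h 2700, 3d 2702) did not pair the tissues and show no cause. When same-numbered retina and RPE libraries were kept together, a test added later, 1 of 56 (highest other 231), 1 of 100 (highest other 1029) and 1 of 100 (highest other 324) splits gave as many calls at 6h, 1d and 3d.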

How the results depend on the processing

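The set term, the within-set fits, median-ratio scaling, library totals, and the fits without 3 RPE libraries or without retina-enriched genes were tests chosen after the results were seen.

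The numbers in the column names were fitted as a replicate block, for NB only with the columns of the same set, since NB numbers repeat between the sets. The replicate block gave 461 and 11 genes in RPE at 1d and 3d against NB (within set, without the block, 452 and 13), 3353 for retina 1d against 6h, 9 for RPE 1d against 6h and 230 for RPE 3d against 1d, and moved no other count by over 1.5 times. For RPE at 6h against NB no paired analysis was possible because the set of the 6h libraries holds 1 NB column. With the block the lens list in retina at 6h had a median log2 fold change of 0.455, the reverse of its direction without it. Between groups the numbers did not pair the libraries. Correlations of deviations between same-numbered libraries ran from -0.277 to 0.297 for retina 1d and NB, from -0.114 to 0.419 for RPE 3d and NB and from -0.538 to 0.281 for retina 1d and 6h, and not every library went best with its own number. Only the 2 numbers of retina 6h and NB (0.261 and 0.685) did so, too few to pair by. Retina and RPE had a correlation of 0.0336 by number, under the limit of 0.1, but in 16 of 16 same-numbered pairs they agreed in genes of the sex chromosomes, so that a number may mark 1 mouse.

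Pseudocounts of 0.1 and 2, no filter, and median-ratio scaling moved none of the 13 counts by over 1.5 times, nor did TMM any of 10. Serpine3 and Cfi lost their calls of a tissue difference at 3d with the pseudocount of 0.1, as they did with DESeq2 and edgeR. A minimum of 2-fold left 455, 980, 379, 528 and 334 genes in the retina contrasts (6h, 1d and 3d against NB, 1d against 6h, 3d against 1d), 119, 370, 171 and 378 in RPE (6h, 1d, 1d against 6h, 3d against 1d) and 899, 1000 and 486 for the tissue difference at 6h, 1d and 3d. The authors' deposited table gave 852, 1839 and 712 in retina and 9, 216 and 13 in RPE at 6h, 1d and 3d after adjustment.

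The method mattered most in RPE. DESeq2 called 1250, 1668, 139, 1652 and 1977 genes in the same 5 RPE contrasts, and edgeR 383 at 6h, every other edgeR count staying within 1.5 times. Array weights gave 3711, 1684, 129, 2871 and 1844 in RPE, and 5368 and 3883 for the tissue difference at 6h and 3d. Fits of the compared groups alone gave 452, 537 and 19 in RPE at 6h, 1d and 3d and 527 for 3d against 1d. Array weights kept the call of every one of 160 genes that met the rule, DESeq2 that of 158 and edgeR of 157.

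Depth sets changed results involving 6h. With a set term retina 1d against 6h had 2427 genes, RPE 6h 32 (5 higher and 27 lower), RPE 1d against 6h 4 (4 and 0), RPE 3d against 1d 2039 and the tissue difference at 6h 887. The within-set counts in RPE were 41 (18 higher and 23 lower), 452 and 13. In RPE at 6h both fits, which compare 6h with NB A1 alone, reversed the median of 6 lists, to 0.0890 for interferon, 0.460 for immediate early, 0.0231 for unfolded protein response, 0.181 for NRF2, 0.491 for cell cycle and -0.0624 for mitochondrially encoded genes, of which immediate early and cell cycle were then called as higher. A set term ended 27 of 160 calls of named genes, most of them in RPE at 6h and RPE 1d against 6h; the cause was not tested. The deeper and shallower NB libraries differed from each other in 227 retina genes, so depth and 6h could be confounded in part; in RPE 1 deeper library cannot show this.

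Library totals in place of the authors' scaling gave 147 genes in RPE at 6h and 299 for 1d against 6h, and other counts moved less than 1.5 times. Without NB B3, 1d 4 and 3d 2, RPE counts were 826 at 6h, 297 for 1d against 6h and 332 for 3d against 1d, and without NB A1 as well 2022, 2031 and 707. At 3d the former fit reversed the medians of RPE identity (-0.166), melanin synthesis (-0.00131), interferon (0.183), cell death (0.0770) and cell cycle (0.483). Without genes at least 4-fold higher in NB retina RPE 6h had 60 (11 higher and 49 lower).

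Leaving out each library in turn moved no retina count by over 1.5 times and ended no call of a named retina gene against NB. In RPE the counts ran from 9 (without 6h 1) to 1011 (without NB A1) at 6h, 618 (without NB B2) to 1426 (without NB B3) at 1d, 15 (without NB B1) to 35 (without NB B4) at 3d, 46 (without 6h 3) to 724 (without 1d 3) for 1d against 6h, and 363 (without 3d 2) to 1196 (without 3d 1) for 3d against 1d. The tissue difference ran from 1536 (without RPE 6h 3) to 3756 (without RPE NB A1) at 6h and from 1322 (without Retina 3d 1) to 3273 (without RPE NB A1) at 3d. The calls of 195 list tests were unchanged in 1651 repeats, gained in 73 and lost in 62. With an estimated correlation 0 of 104 called lists passed in camera, while the glial and microglial tissue differences did.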

Other observations

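Krt5 ranked 4 by mean CPM among genes of NB RPE, ahead of Rpe65 at 32. The 18 surface markers together reached at most 0.00419% of CPM in any retina library. The cause of their share in RPE was not tested.

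The first principal component held 39.1% of variance in retina and 33.9% in RPE, where NB A1, NB B3, 1d 4 and 3d 2 stood apart on it. Sex chromosome genes loaded highly on it in RPE and the second in retina. In RPE, Trhde, Itgb8, Rpe65 and Inpp5k loaded at its positive end and Muc5ac, Ltf and Sprr1a at its negative end. Xist led the NB end of the first in retina. Sex was not adjusted for.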
